A study of Mus musculus with 9 samples.

How the data were processed

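Total RNA from red-cell-lysed whole marrow of 8 mice (5 untreated, 3 given 5-FU) was profiled on 9 bead arrays in 2 batches. The authors deposited a table of normalized values, a table of raw values and a series value table. Per the labels, the 2 batches are not biological replicates, so the 2 arrays of 5-FU animal 1 were averaged on the log2 scale and counted as 1 animal. The deposited normalized values are log2 fluorescence that the authors scaled assuming an equal total miRNA signal per array, per the series design text. In the deposited table the totals were 401283 to 402143 in batch 1 and 355655 to 362039 in batch 2. The value 3 is a floor shared by 46.8% of the values. The deposited raw table holds bead fluorescence intensity per probe with no normalization, per the file headers, beside 3 background wells. The deposited p-value and false discovery rate columns come from the authors and cover 168 probes they marked as passing a signal threshold. The series value table equals the normalized table at every probe. Software and versions of the upstream steps are not given in the sources used here.

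The deposited values were compared with the raw table. In batch 1 each normalized column equals the log2 of raw fluorescence minus the higher of the 2 water wells plus a constant for each of the 2 bead pools, but all 5 untreated columns match a raw column of another untreated animal. Group membership is not affected, and values per untreated animal from the raw and the normalized tables were therefore not paired. In batch 2 the normalized columns match raw columns of the same name but carry an additional probe-specific term, shared by the 3 arrays, with an SD of 0.51 on the log2 scale over 155 probes. Its origin is not given in the sources used here. The deposited p-values equal those of a test with unequal variances on 5 untreated and 4 treated arrays, so the 2 arrays of 5-FU animal 1 counted separately there. The authors' deposited table gave a false discovery rate under 0.05 for 92 of 168 probes, of which 89 were also called here.

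Control beads (12 rows) were left out, leaving 582 miRNA probes. A probe was tested if it lay above the floor in at least 3 of 8 animals, which kept 379 probes. Of these, 217 are named for mature mouse miRNAs, 100 carry a human name only and 62 a hairpin name, with some in both of the last groups and a few under retired names. Hairpin-named and retired probes were kept under their own names and never taken for a mature arm. Groups were compared with limma (version 3.58.1, R 4.3.3) by lmFit and eBayes with group as the term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Where all animals of a group lie at the floor, the change is against the floor and its true size is not known. A probe at the floor in all 5 untreated animals was tested only if all 3 treated animals lay above it. The direction of such a probe was thus set by the filter. Fixed lists (16, of which 14 had at least 3 tested members) were tested with camera at a preset correlation of 0.01. Array totals and detection were compared by exact permutation over all 56 splits. Lists, the tests of the comparisons, the alternatives not named below as added and the rule for named miRNAs were set before the data were examined. That rule took the 12 largest rises and 12 largest falls past the threshold with all treated animals on the same side of all untreated ones, up to 4 members per list, and 9 miRNAs of prior interest (miR-150, miR-223, miR-142-3p, miR-451, miR-125b, miR-126, miR-155, miR-181a and miR-34a), 76 probes in all. Another 26 miRNAs or hairpin probes named in the text fall outside it and were chosen after their values were seen. These are miR-17, miR-18a, miR-19a, miR-20a, miR-92a, miR-106a, miR-107, miR-125a-5p, miR-130a, miR-130b, miR-196b, miR-199a-5p, miR-199b-5p, miR-214, miR-215, miR-221, miR-222, miR-342-3p, miR-362-5p, miR-423-3p, miR-424, miR-501-5p, miR-503, miR-542-3p, mir-450a and a human-named probe for miR-215. Listed names without an arm were matched to the major arm, and those choices of arm were made after the probe names were seen.

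The main fit was tested on simulated data for the 5-FU comparison over 379 probes in 20 runs. Of probes changed by 0.5, 1 and 2 on the log2 scale, 26.2%, 55.0% and 79.2% were recovered, and 5.45% of calls were false. A list shifted by 1 was called by camera in 20 of 20 runs, with 2 calls of other lists. The simulated noise was independent between probes and held no batch difference. These shares therefore do not cover correlated list members or a batch that goes with the group. Alternatives covered the array used for 5-FU animal 1, batch terms, the test, the moderation, other normalizations of the raw or deposited values, filters, leaving out each animal and the replicate block. Control beads, water wells, the authors' probe set and equal totals of the deposited values entered alternatives chosen after seeing the data. miRNA gene symbols were matched to the GRCm38.p6 gene table for 209 of 217 mature mouse probes, only to find neighbouring genes.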

Results

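MicroRNA (miRNA) abundance was measured in whole bone marrow of 8 female C57Bl6/J mice aged 6 weeks. Of these animals, 5 were untreated and 3 had received 5-fluorouracil (5-FU) at 150 mg/kg into the peritoneum, with marrow taken at day 4. 5-FU is an antimetabolite that kills dividing cells and so depletes cycling marrow cells while sparing resting stem cells. Red cells were lysed before RNA isolation. The assay was a bead array, in which miRNAs are ligated to adaptors, amplified, captured on probe-coupled beads and read as fluorescence. The 9 arrays were run in 2 batches. Batch 1 held all 5 untreated animals and 5-FU animal 1, and batch 2 held 5-FU animals 1, 2 and 3, so 5-FU animal 1 was profiled in both. The number of arrays limits the precision of every value below. Summed raw fluorescence over the 582 miRNA probes ranged from 336483 to 679696 units per array.

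The first comparison asked which miRNAs differed in marrow at day 4 after 5-FU. miRNAs of the p53-linked miR-34 family, vessel-associated miR-126, smooth-muscle miR-143 and miR-145, and the skeletal muscle miRNAs miR-1, miR-133b and miR-206 were higher in treated marrow. The miR-181 family, many members of the miR-17~92 clusters, miR-128, miR-130b, miR-351 and miR-338-3p were lower. Of 379 probes tested, 154 differed (limma, Benjamini-Hochberg adjusted p under 0.05), of which 59 were higher and 95 lower. Among the 59 rises, 33 were probes at the detection floor (log2 value 3) in all 5 untreated animals, with a median change of 0.13 and a highest change of 0.40 on the log2 scale. In 31 of those 33 the batch 1 array of 5-FU animal 1 was at the floor too. Among the 158 probes above a log2 value of 7 in at least 3 animals, 18 rose and 70 fell. The split of calls moved with the scaling. The deposited totals were lower in batch 2 than in batch 1, by 0.17 on the log2 scale, and after rescaling them to an equal total 76 probes rose and 76 fell. Raw values scaled to an equal total gave 33 rises and 37 falls, quantile normalization of the raw values gave 48 and 43, centring of the deposited values on the median gave 118 and 55, and scaling to the control beads gave 17 and 10. The median change over all tested probes was -0.16 in the deposited values, 0.31 after centring and -0.03 after scaling to the control beads. With batch as a term over all 9 arrays, 37 probes passed (9 rises and 28 falls). Batch 2 held no untreated array, so the group change in that fit equals the change within batch 1. It rests on 1 treated array, and the 2 arrays of 5-FU animal 1 counted separately in its error. Passing with batch as a term, here and below, is therefore not a check separate from batch 1. Within batch 1, where 1 treated array stood against 5 untreated, 12 passed, and the changes correlated with those over all animals at r = 0.93 across the 379 probes, which are not independent replicates. Both sets of changes share the untreated arrays and the batch 1 array of 5-FU animal 1, so part of this agreement is built in.

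**Figure D1:**
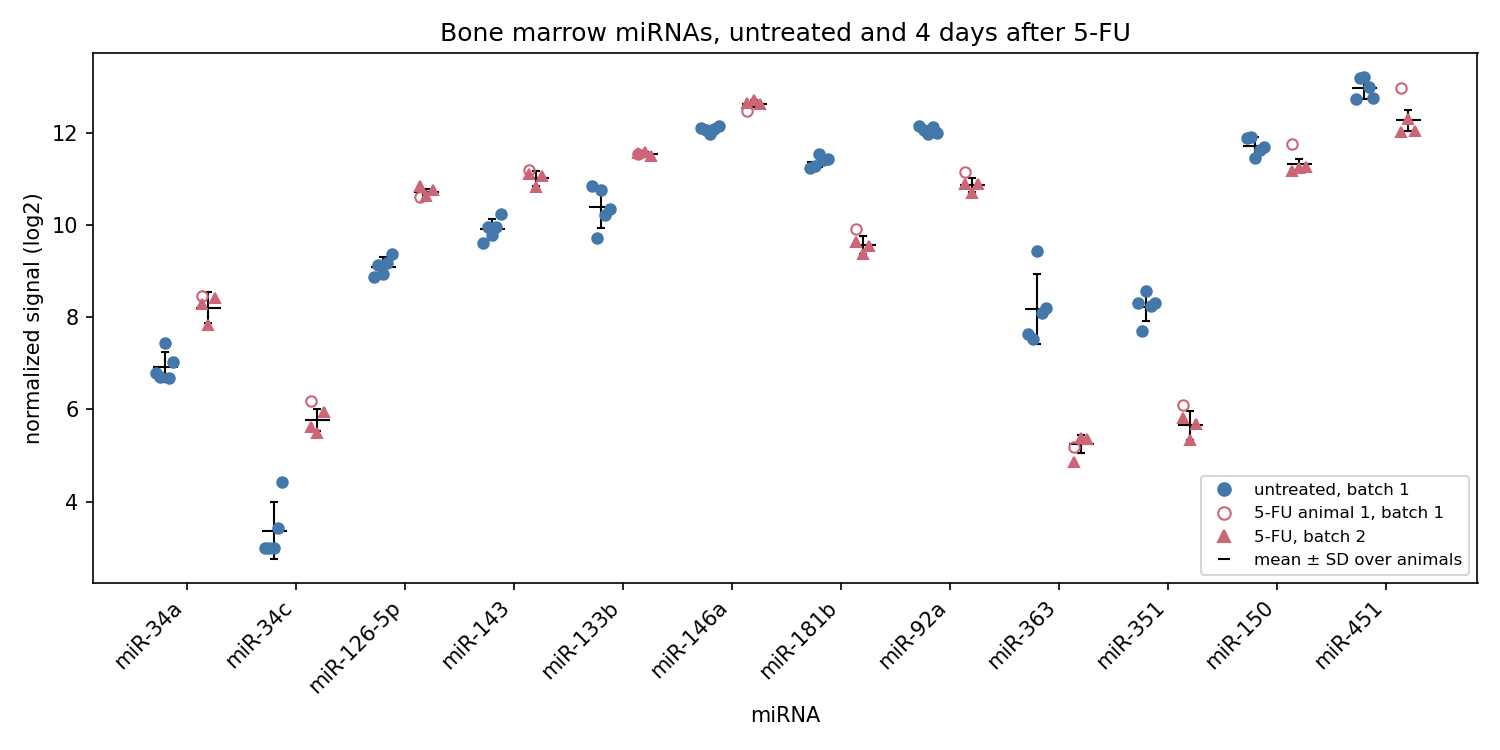
Normalized log2 signal (y axis) of 12 miRNAs (x axis) on each array. Filled blue circles are the 5 untreated animals, open circles the batch 1 array of 5-FU animal 1 and triangles the batch 2 arrays, with bars for the mean ± SD over animals. The batch 1 array of 5-FU animal 1 lies with the other treated arrays for miR-34a, miR-126-5p, miR-181b and miR-92a, and with the untreated animals for miR-150 and miR-451.

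The 12 largest rises with all 3 treated animals above all 5 untreated ones were led by miR-34c. Its log2 signal was 3.37 ± 0.61 (SD, n = 5) in untreated and 5.77 ± 0.24 (SD, n = 3) in treated marrow, a change of 2.40 (SE 0.36, limma adjusted p = 0.00312), with 3 of the 5 untreated animals at the floor. miR-34a, a direct transcriptional target of p53, rose from 6.93 ± 0.32 (n = 5) to 8.21 ± 0.33 (n = 3), a change of 1.28 (SE 0.22, limma adjusted p = 0.00554). A hairpin-named probe for mir-34b rose by 1.24 from a level at the floor in 4 untreated animals. miR-126-5p, from an intron of the endothelial gene Egfl7, rose from 9.10 ± 0.20 (n = 5) to 10.71 ± 0.07 (n = 3), a change of 1.61 (SE 0.12, limma adjusted p = 0.000279). The other members of this set were miR-218 (1.63), miR-196a (1.41), a human-named probe for miR-606 (1.38, from 3.53), a hairpin-named probe for mir-199b (1.37), a hairpin-named probe for mir-133a (1.19), miR-133b (1.16), miR-143 (1.11) and miR-145 (1.06). With batch as a term, the group change rests on the 1 treated array of batch 1. In that fit miR-34c, miR-34a, miR-126-5p, miR-143, mir-133a and mir-34b kept an adjusted p under 0.05. miR-218, miR-196a, miR-133b, miR-145, mir-199b and miR-606 did not, with within-batch changes of 1.45, 1.25, 1.15, 0.96, 0.98 and 1.55.

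The 12 largest falls with separated groups began with a retired probe named old_j-mir-16, which fell by 3.37 (SE 0.41, limma adjusted p = 0.00154). The current miR-16 probe gave a change of 0.34 (SE 0.16, adjusted p = 0.137) and is not the same measurement. miR-298 fell from 6.79 ± 0.18 (n = 5) to 3.66 ± 0.74 (n = 3), with 1 treated animal at the floor, and miR-363 fell by 2.93 (SE 0.43, adjusted p = 0.00312). miR-351, which lies on the X chromosome, fell from 8.23 ± 0.32 (n = 5) to 5.65 ± 0.31 (n = 3), a change of -2.58 (SE 0.22, adjusted p = 0.000488). Both miR-128 probes fell, with changes of -2.29 and -2.27. miR-326 (-2.24), miR-129-3p (-2.55), miR-877 (-2.46), a retired probe named old_r-miR-333 (-2.42), a hairpin-named let-7d probe (-2.37) and a human-named mir-500 hairpin probe (-2.71) completed the set. With batch as a term, miR-877, let-7d (hairpin) and mir-500 (hairpin) no longer passed (adjusted p = 0.159, 0.356 and 0.629). miR-298, miR-129-3p, let-7d (hairpin) and mir-500 (hairpin) were at the floor in 1 of 3 treated animals.

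The lists fixed beforehand asked which classes of marrow miRNA moved together. In the list of the miR-17~92 cluster and its paralogs, which are known for high levels in proliferating progenitors, 9 of 14 tested members fell, 0 rose and 5 did not pass, and 11 fell when adjusted over the list alone. miR-92a fell from 12.06 ± 0.08 (n = 5) to 10.87 ± 0.16 (n = 3), miR-18a fell by 1.20, miR-20b by 1.46 and miR-19a by 0.80. Within batch 1 miR-20b and miR-19a were at -0.70 and -0.48, and neither passed with batch as a term (adjusted p = 0.0710 and 0.165). miR-17 itself (-0.27) and miR-20a (-0.24) did not pass. The mean change of the list was -0.90 (SD 0.79 over 14 members, camera adjusted p = 0.00201), and the call was lost with an estimated correlation (adjusted p = 0.577). Within batch 1 its mean was -0.57 (camera adjusted p = 0.152), and with batch as a term the adjusted p was 0.128, with 4 members still lower (miR-92a, miR-18a, miR-106a and miR-363). After rescaling of the raw values the mean was -0.34 with quantile (camera adjusted p = 0.00226), -0.36 with an equal total (adjusted p = 0.0741) and -0.26 with the control beads (adjusted p = 0.157), so the call was lost in the last pair. It was also lost among probes above log2 7 (adjusted p = 0.0957).

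In the stromal and mesenchymal list, 3 of 7 members rose, 0 fell and 4 did not pass, with the same count of 3 adjusted over the list alone. miR-143 rose from 9.91 ± 0.23 (n = 5) to 11.01 ± 0.17 (n = 3), and miR-145, which is made from the same primary transcript, from 8.18 ± 0.50 to 9.24 ± 0.12. miR-152 (0.54), miR-199a-5p, miR-199b-5p and miR-214 did not pass. The list's mean change was 0.76 (SD 0.53, camera adjusted p = 0.0190), and it was lost with an estimated correlation (adjusted p = 0.577). Without 5-FU animal 1 the adjusted p was 0.191, and without untreated animal 3 it was 0.0504. In raw values the mean was 0.92 with quantile (camera adjusted p = 0.00676) and 0.92 with an equal total (adjusted p = 5.5e-05). Scaled to the control beads it was 1.01 (adjusted p = 0.00021). The call with an equal total was lost with an estimated correlation (adjusted p = 0.268). Within batch 1, with 1 treated array, the mean was 0.70 (camera adjusted p = 0.0458), and with batch as a term the adjusted p was 0.0252. In the skeletal muscle list, a tissue beside the marrow, all 3 tested members rose and all 3 passed when adjusted over the list alone. These were miR-1 (0.80), miR-133b (1.16) and miR-206 (1.04), of which 0 passed singly with batch as a term. In the deposited values the list did not pass over all animals (camera adjusted p = 0.0750) and passed with batch as a term (adjusted p = 0.0302). With an estimated correlation over all animals the adjusted p was 0.577. In raw values its mean was 1.12 with quantile (camera adjusted p = 0.0405) and 1.16 with an equal total (adjusted p = 0.00144). Scaled to the control beads it was 1.26 (adjusted p = 0.00372). The call with an equal total was again lost with an estimated correlation (adjusted p = 0.268).

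In the lymphocyte list, 6 of 10 members fell, 1 rose and 3 did not pass, with the same counts adjusted over the list alone. All 4 miR-181 members fell, with changes of -0.92 for miR-181a, -1.80 for miR-181b, -2.15 for miR-181c and -2.22 for miR-181d. miR-181 is high in early lymphoid and thymic cells, and is expressed in other blood cells as well. miR-342-3p fell by 0.86, but was at 0.16 in raw values with an equal total and 0.25 with quantile, and miR-29c rose by 0.34. miR-150, abundant in mature B and T cells, passed with a change of -0.39 (SE 0.12, limma adjusted p = 0.0389) but was at 0.04 within batch 1 and with batch as a term (adjusted p = 1), and its sign turned under each rescaling of the raw values and under median centring. The list's mean was -0.80 (camera adjusted p = 0.115). With batch as a term 4 members still fell (miR-181a, miR-181b, miR-181c and miR-342-3p). miR-181d did not pass there, with a change of -1.99 within batch 1. In raw values its mean was -0.36 with an equal total, -0.35 with quantile and -0.26 with the control beads, with medians of -0.04, -0.04 and 0.06.

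The p53 and DNA damage list split. miR-34a and miR-34c rose, miR-192 (-1.60), miR-194 (-0.82) and miR-107 (-0.70) fell, and miR-215 (-0.60, from 4.16) did not pass, with the same counts adjusted over the list alone. A human-named probe for miR-215, not in the list, fell by 1.64 from 8.36 (limma adjusted p = 0.000279, with batch as a term 0.0206) but was at 0.010 in quantile normalized raw values. The mean change was -0.01 (camera adjusted p = 0.850). Both rises passed with batch as a term and the 3 falls did not, with miR-192 at -0.57 within batch 1, and miR-194 changed sign in 4 rescalings of the raw values. In the stem and progenitor list, 3 members rose and 5 fell of 13, with the same counts adjusted over the list alone, and with batch as a term 1 rose (miR-126-5p) and 1 fell (miR-125a-5p). miR-126-3p (0.90), miR-126-5p and miR-196a rose, while miR-10a (-0.91), miR-10b (-1.18), miR-196b (-0.79), miR-125a-5p (-0.51) and miR-130a (-0.55) fell. miR-125b-5p, which is high in stem cells, gave -0.19 (adjusted p = 0.319). Within batch 1 miR-10a and miR-10b were at -0.24 and -0.29, and miR-10b was above 0 in all raw rescalings. miR-125a-5p and miR-130a were at 0.08 and 0.15 in raw values scaled to the control beads. The list's mean was -0.04 in the deposited values (camera adjusted p = 0.850) and 0.47 in raw values with an equal total (camera adjusted p = 0.00144, and adjusted p = 0.394 with an estimated correlation). With quantile it was 0.44 (camera adjusted p = 0.110).

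The remaining lists had mean changes between -0.34 and 0.33. In the granulocyte and monocyte list, 1 of 8 members fell (miR-338-3p, -1.79, SE 0.14, limma adjusted p = 0.000369) and 0 rose. The myeloid miR-223 stood at 12.72 ± 0.33 (n = 5) and 12.56 ± 0.10 (n = 3), a change of -0.16 (adjusted p = 0.522). In the erythroid list 2 of 6 fell, miR-183 (-1.78) and miR-451 (-0.70), while miR-144 (-0.12) and miR-486 (0.54) did not pass. miR-183 was low, at 5.37 in untreated and 3.59 in treated marrow, the latter near the floor of 3. miR-451 was at -0.01 within batch 1. In the inflammatory list 1 of 7 rose, miR-146a (0.56, SE 0.05, limma adjusted p = 0.000698), and miR-155 gave 0.29 (adjusted p = 0.387). In the let-7 family 3 of 9 fell and 4 fell when adjusted over the list alone, led by miR-98 (-0.91), but let-7b (-0.19) and let-7d (-0.28) turned above 0 under some scalings. Of the miR-15/16 family 0 of 5 passed. In the list of tissues outside the marrow, 1 of 10 rose (miR-124, 0.40, at the floor in all untreated animals) and 1 fell (miR-203, -0.97). In the miR-30 family 1 of 5 fell (miR-30d, -0.28), and in the miR-29 family both tested members rose, miR-29b by 0.32 and miR-29c by 0.34. In the Dlk1-Dio3 cluster 1 of 24 rose (miR-154, 0.85, from 2 untreated animals at the floor), and 0 did when adjusted over the list alone. The pan-haematopoietic miR-142-3p (0.34) and miR-142-5p (-0.15) did not pass. Except where given, these counts were equal when adjusted over the list alone. With batch as a term, miR-338-3p, miR-183 and miR-146a still passed, while miR-451, miR-98, let-7b, let-7d, miR-124, miR-203, miR-30d, miR-29b, miR-29c and miR-154 did not. None of these lists passed camera (lowest adjusted p = 0.316), and the miR-29 and pan-haematopoietic lists had too few tested members for it. The test fry, an alternative to camera, called the granulocyte and monocyte list (fry adjusted p = 0.0256) and the let-7 list (0.0335) lower. It also called the erythroid list lower and the inflammatory list higher (fry adjusted p = 0.0448 for each).

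**Figure D2:**
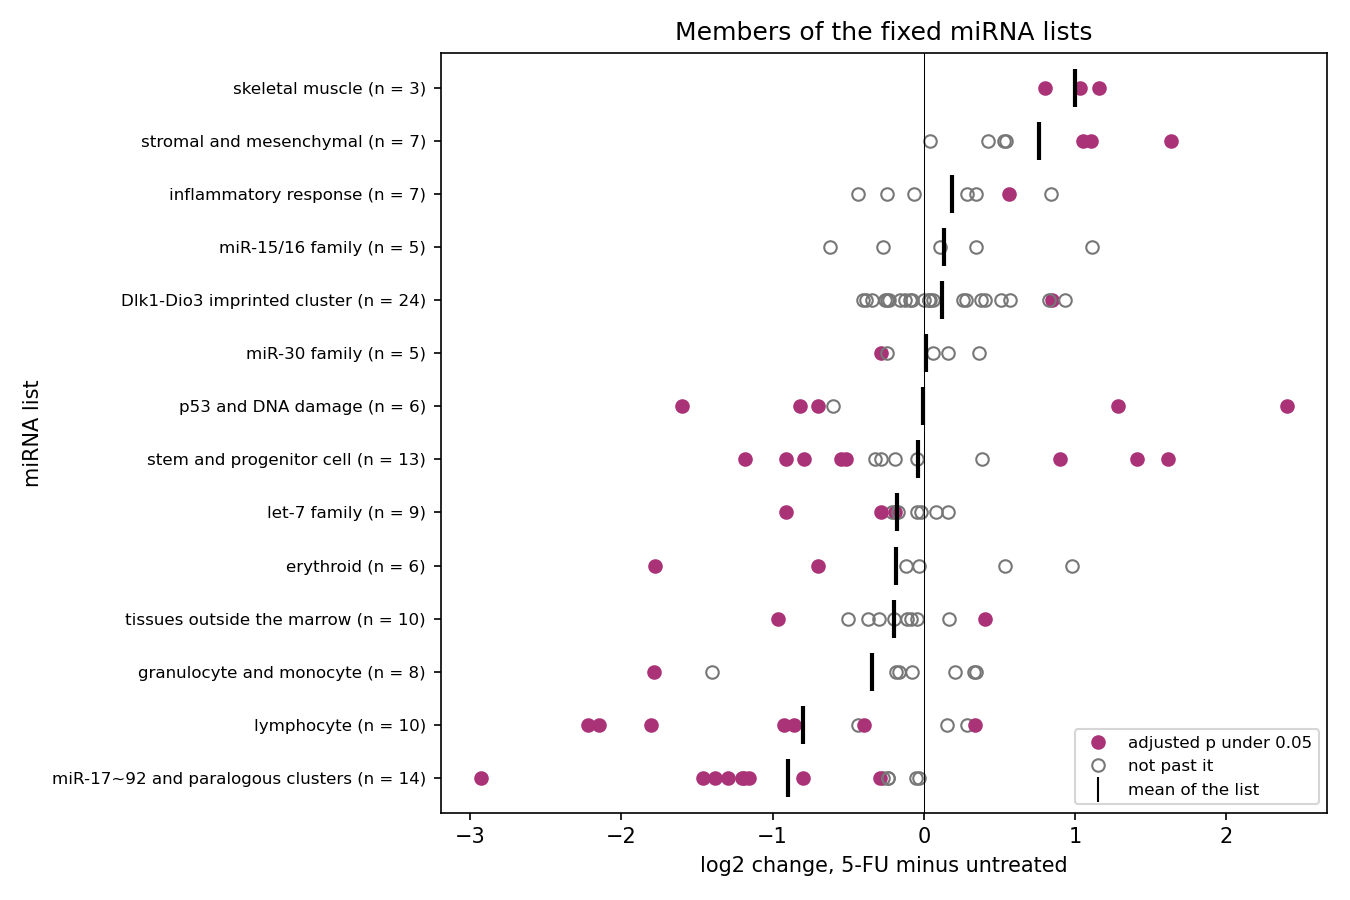
Log2 change, 5-FU minus untreated (x axis), of each tested member of the 14 lists with at least 3 tested members (y axis). Filled points have an adjusted p under 0.05 (limma), open points do not, and the black bar is the mean of the list. All 3 skeletal muscle members and 9 of 14 members of the miR-17~92 list are filled.

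The third comparison asked whether the arrays differed in total signal and in the number of probes detected. The log2 total raw signal was 18.86 ± 0.37 (SD, n = 5) in untreated and 18.99 ± 0.17 (SD, n = 3) in treated marrow, a difference of 0.13 (exact permutation test over 56 splits, two-sided, p = 0.643). The 2 arrays of 5-FU animal 1 lay further apart than the groups, at 18.55 in batch 1 and 19.15 in batch 2. Probes above the floor numbered 293 ± 27.7 (n = 5) and 339 ± 29.0 (n = 3), a difference of 46.2 (exact permutation p = 0.0714, two-sided). 5-FU animal 1 had 259 such probes on its batch 1 array and 354 on its batch 2 array, and the untreated animals had 266 to 338. Probes with a log2 value above 7 were fewer in treated marrow, at 137 ± 3.51 against 156 ± 9.17 (exact permutation p = 0.0357, two-sided, the smallest this design allows), and 5-FU animal 1 had 138 and 136 on its 2 arrays.

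Within 5-FU animal 1, the batch 2 array minus the batch 1 array had a median difference of 0 and an SD of 0.35 over the 379 tested probes. In the fit of batch and group over all 9 arrays, which sets 1 treated array in batch 1 against 3 in batch 2, the batch term passed in 55 probes (limma adjusted p under 0.05), against 37 for the group. The difference exceeded 1 on the log2 scale in 8 probes. The SD of the change between groups was 0.82. The 2 arrays correlated at r = 0.995 across probes, which are not independent replicates, in deposited values whose batch 2 part carries a probe-specific term. Over 155 probes that term correlated at r = 0.76 with the batch difference of the raw values of this animal, which had an SD of 0.43. Batch 2 minus batch 1 was -0.58 for miR-150, -0.95 for miR-451, -1.29 for miR-195, -1.26 for miR-192, -1.12 for miR-10b and -0.84 for miR-10a, against group changes of -0.39, -0.70, -0.62 (not passed), -1.60, -1.18 and -0.91.

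**Figure D3:**
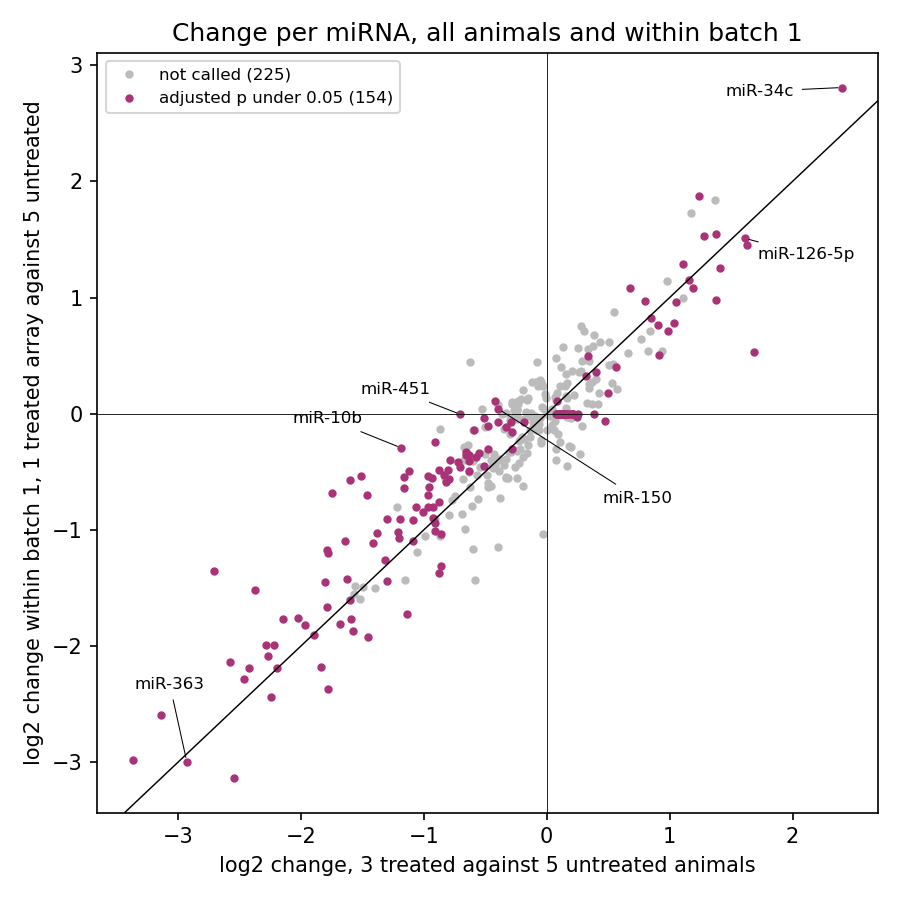
Log2 change per probe over all animals (x axis) against the change within batch 1, the batch 1 array of 5-FU animal 1 minus the mean of 5 untreated animals (y axis), for 379 tested probes. The diagonal marks equal change, the purple points have an adjusted p under 0.05, and miR-150, miR-451 and miR-10b lie nearer 0 on the y axis than on the x axis.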

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

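The tests of the batch, of the probe-specific term, with the control beads and of the cell types below were chosen after the results were seen, while the split test was not. Gaps in the 5 untreated animals were checked for 78 measures, and 8 stood out, where chance gives about 1 in 20. Untreated animal 3 lay apart for miR-877 (9.13, others 7.02 to 7.35), miR-183 (6.02, others 5.17 to 5.26) and miR-30c (12.01, others 12.43 to 12.55). Untreated animal 1 lay below the others for the mir-199b hairpin probe (8.61, others 9.32 to 9.58), old_r-miR-333 (9.55, others 10.38 to 10.68) and miR-152 (8.38, others 9.16 to 9.37). Untreated animal 2 was at 10.42 for miR-18b (others 11.18 to 11.49), and untreated animal 5 at 3.11 for the mir-34b hairpin probe (others at the floor of 3).

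The first pattern weighed is the number of miRNAs that differ. The real split of the 8 animals gave 154 probes, and the highest of the other 55 splits gave 3. So 1 of 56 splits was as large, the smallest share possible here, which argues against chance without excluding it. The real split also follows the batches, apart from the batch 1 array of 5-FU animal 1, so the count does not tell treatment from batch. The changes of 5-FU animal 1 in batch 1 against 2 untreated animals correlated with those of 5-FU animals 2 and 3 against the other 3 at a median r of 0.80 over 10 divisions, but the probe-specific term in batch 2 follows the raw batch difference of 5-FU animal 1 (r = 0.76) and may build this in. In raw values without the term the median r was 0.69 with an equal total, 0.81 with quantile and 0.70 with water wells (0.86, 0.88 and 0.84 over the 158 probes above log2 7). The lowest were 0.361, 0.739 and 0.610. With an untreated array in place of 5-FU animal 1 the highest were 0.339, 0.289 and 0.210, narrowly below in the first. A stricter bound on the lowest r, tried first, was not met with an equal total. The comparison with an untreated array replaced it after these values were seen. With quantile and water wells the values argue against a batch difference as the whole cause, and less clearly with an equal total. A batch difference stays open as part of the cause. In raw values with water wells subtracted, 74.7% of the 154 kept their direction, 25 had no change and 14 turned. Of 56 calls there, 47 were among the 154 (30.5% of them). Deposited values rescaled to an equal total, which carry the term, gave 152 calls, so the count was much lower without it. These raw values also lack the constant for each bead pool, so the part due to the term alone stays open.

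The second pattern is lower miR-150 and miR-451. Between the 2 arrays of 5-FU animal 1, miR-150 differed by -0.58 and miR-451 by -0.95, against group changes of -0.39 and -0.70, and both batch 1 values lay inside the untreated range. These are deposited values whose batch 2 part carries the probe-specific term, so they do not tell a profiling difference from that term. In raw values without the term miR-150 was not lower, at 0.10 with an equal total, 0.12 with quantile and 0.20 with control beads. miR-451 turned above 0 only without normalization (0.0029). The values fit a difference between the batches in the deposited values as the cause. Its source stays open, as does a treatment effect.

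The third pattern is higher stromal and muscle miRNAs. Scaled to the control beads, the 10 tested members rose by 1.09 on average (SE 0.20), which argues against the equal-total normalization as the cause. A lower share of blood-forming cells would raise both lists alike, and over members with log2 above 7 the muscle change minus the stromal change was 0.12 (SE 0.33), too imprecise to decide. Over 4 such members of the list of tissues outside the marrow the change was -0.46 (SE 0.19), but 0.27 (SE 0.04) in quantile normalized raw values, and the cells that give this signal in marrow are not known, so it does not decide either. More muscle carried over in the treated samples could add miR-1 and miR-133b, and the stromal list's test within batch 1 (limma camera adjusted p = 0.0458, unadjusted 0.00327) rests on 1 treated array and decides nothing. These sources and a larger share of marrow stroma after 5-FU cannot be told apart, and the last stays a hypothesis.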

How the results depend on the processing

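The alternatives with control beads, water wells, equal totals of the deposited values, the authors' probes and untreated animal 3 left out beside the batch 1 array of 5-FU animal 1 were chosen after seeing the data, as was batch as fixed terms for the count of miRNAs, but not for the lists. A batch fit with the animal as a random block, and the 9-array fit with that block, could not be fitted, since only 5-FU animal 1 has 2 arrays. The series value table was identical and not run separately. Counts were taken as similar within 1.5 times. The methods' t-test gave 175 probes after Benjamini-Hochberg, eBayes with trend and robust 170, no filter 168, the batch 2 array of 5-FU animal 1 alone 185, median centring 173, deposited values with equal totals 152 and normexp with quantile 103. The 154 probes moved to 37 with batch as a block, 12 within batch 1, 95 with 5-FU animal 1 by its batch 1 array, 70 with equal-total raw values, 91 with quantile, 3 without normalization, 88 above log2 7, 100 above the floor in all animals, 92 with the deposited p-value's test, 89 with limma on the authors' probes, 56 with water wells subtracted and 27 with control beads. Leaving out untreated animal 3 with 5-FU animal 1 by its batch 1 array gave 107. Leaving out each animal gave 95 to 168, and without 5-FU animals 2 or 3 95 and 97. The smaller counts under the filters and the authors' probes go with fewer probes tested, and the cause of the others was not tested. Same-numbered animals correlated in their deviations at 0.05, 0.35 and 0.17. In that check animals 2 and 3 of each group, but not animal 1, correlated best with their own number. The untreated numbers also differ between the raw and the normalized values, so whether the numbers pair the animals stays open. The replicate block gave 52 probes on 6 animals.

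Of the lists, 2 passed camera. The estimated correlation left 0, with all adjusted p at 0.577 or above, and fry called 8. An estimated correlation in equal-total raw values, added after seeing the data, left 0 too (lowest adjusted p = 0.268). Within batch 1, 1 passed, and leaving out each animal left 1 to 3, with 1 without untreated animal 3 and 1 without 5-FU animal 1. The stem and progenitor mean turned to 0.47 with an equal total and 0.57 with control beads. It was also above 0 with quantile (0.44), within batch 1 and with batch as a block (0.15), and with the replicate block (0.08). Without untreated animal 5 it was 0.02, and without 5-FU animal 2 it was 0.05. The number of probes above the floor differed by 46.2, by 62 with the batch 2 array of 5-FU animal 1 (exact permutation p = 0.0357), by 30.3 with its batch 1 array (p = 0.393) and by -19.3 at log2 above 7. Over the 29 alternatives, 2158 checks of the 76 named probes left 1760 on the same side of the threshold. Of the rest, 312 lost the threshold, 46 gained it and 40 turned in sign. For the 26 named outside the rule, 741 checks gave 592, 108, 23 and 18. A turn in sign was counted only where the probe passed in the main fit or in the alternative. Probes that passed in neither were counted as on the same side, whatever their sign.

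Turned values on the log2 scale, for probes that passed in the main fit or in the alternative, were as follows, and the cause was not tested. Others turned without passing in either, among them miR-195 at 0.45, miR-223 at 0.12 and miR-144 at 0.27 within batch 1. miR-150 was 0.042 with batch as a block and within batch 1, 0.10 with an equal total, 0.12 with quantile, 0.23 without normalization, 0.076 with median centring, 0.13 with normexp, 0.093 with water wells and 0.20 with control beads. miR-451 was 0.0029 without normalization. miR-10b was 0.13 with an equal total, 0.073 with quantile, 0.26 without normalization, 0.048 with normexp, 0.16 with water wells and 0.23 with control beads. miR-194 was 0.10 with an equal total, 0.23 without normalization, 0.11 with water wells and 0.20 with control beads. let-7b was 0.076, 0.0030, 0.21, 0.28, 0.071 and 0.17 with an equal total, quantile, no normalization, median centring, water wells and control beads. let-7d was 0.10, 0.19 and 0.071 with no normalization, median centring and control beads, and miR-30d 0.011 and 0.19 with the first pair of these. miR-195 was 0.76, 0.74 and 0.71 with an equal total, quantile and normexp, miR-124 -0.13 and -0.030 with an equal total and control beads, miR-29b -0.0012 with normexp, miR-200c 0.30 with normexp and miR-200b 0.66 and 0.56 with quantile and normexp. miR-342-3p was 0.16, 0.25, 0.29, 0.24, 0.16 and 0.26 with an equal total, quantile, no normalization, normexp, water wells and control beads. miR-125a-5p was 0.11 and 0.084 with no normalization and control beads, and miR-130a 0.055, 0.18, 0.053 and 0.15 with an equal total, no normalization, water wells and control beads. miR-106a was 0.11 and 0.078 with no normalization and control beads. The human-named miR-215 probe was 0.010, 0.033, 0.037 and 0.0027 with quantile, no normalization, normexp and control beads. Low signal over background limits probes near the floor.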

Other observations

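The tests in this part were chosen after the values were seen, and the miRNAs named here were too. Several falls were of miRNAs that the lists did not hold, some of them with neighbouring genes. The X-linked miR-221 fell from 11.51 ± 0.17 (SD, n = 5) to 10.30 ± 0.15 (SD, n = 3), a change of -1.21 (limma adjusted p = 0.000698), and miR-222, from the same transcript, by 0.63. miR-130b changed by -1.97, miR-423-3p by -1.79 and human-named probes for miR-362-5p and miR-501-5p, whose genes neighbour each other on the X chromosome, by -2.03 and -1.84. miR-351 fell by 2.58, and of its neighbours a hairpin-named probe for mir-450a fell by 1.09 (adjusted p = 0.00308) while human-named probes for miR-503 (-1.40, adjusted p = 0.0550) and miR-424 (0.21, adjusted p = 0.708) did not pass. miR-542-3p, at the floor in all untreated animals, cannot show a fall.

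miRNAs with neighbouring genes may change alike through a shared transcript. Over 122 pairs of neighbouring miRNA genes with different numbers, of 85 miRNAs and within 10 kb, the mean absolute difference in log2 change was 0.57 against 0.78 for reassigned values (one-sided permutation p = 0.0017), and 0.0394 within batch 1. Without the Dlk1-Dio3 genes the p was 0.0246 over 61 pairs. In a matching by any synonym, an outdated synonym places miR-298 beside other genes than its own, and the p is then 0.0566 over 128 pairs, so the result rests on how that miRNA is placed. Without the miR-17~92 list the p was 0.0082 over 96 pairs. Both members had the same sign in 76 of the 122 pairs. The count for reassigned values was not computed. The median change over all tested probes was -0.16, so unrelated pairs can share a sign too. Pairs share members and some probes of related sequence may cross-react, which was not tested.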
